A study of Ampelisca abdita with 151 samples.

How the data were processed

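RNA was measured in 151 samples of Ampelisca abdita from 29 groups, with 155 scanner files, since ER 40% replicate 1 had 2 arrays and replicate 2 had 4. Per the labels, 10 animals per jar were kept for 7 days on 20 g of sediment under 60 ml of aerated seawater at 30 ppt, and animals not found were counted as dead. In ER 40% (replicates 1 and 3), ER 6.25% and Mdl.DDT 2 tubes came from the same jar, and the tests treat them as independent. Per the protocol, RNA came from tubes of at most 3 animals in the sediment exposures and, in the model toxicant exposures, from a single tube with all survivors of a jar, and 90 ng of it was labeled. The sample labels of Mdl.DDT contradict the latter, since they list 2 tubes of 1 jar. Mdl.BaP replicate 5, Mdl.Deg replicate 6 and Mdl.GrandMix replicate 5 are also labeled as tube b, which casts doubt on a single tube there. The labels give 5 treatment batches, 2 hybridization batches of 79 and 72 arrays, and 2 labeling batches, the second with 15 arrays. The arrays lay on 26 slides and, per the file headers, were scanned in 4 batches.

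Each scanner file holds, per the file headers, a spot intensity in scanner brightness made with Feature Extraction 9.5.1.1, which subtracted background and removed spatial trends within the array but did not normalize between arrays. The same files hold the intensity of the unprocessed spot and of its local background, and, as another kind of value (other) per the file headers, flags for spots that are well above background, saturated or uneven. The deposited value table holds an intensity per probe and sample on a linear scale, for which the authors' processing steps are not stated. Its values correlated with their own arrays at a median r of 0.998 across probes (lowest 0.967), against 0.941 with other arrays; probes are not independent replicates. Its column medians lay between 80.8 and 86.8, so it had been adjusted between arrays. It was used only as an alternative source of values.

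The 7351 probes of 60 bases are identified by clone names, except 22 without one, and no gene name or description is given for any probe. The processed intensity was averaged over the spots of a probe on the log2 scale, leaving out spots marked as outliers unless all spots of the probe were, and the array's 75th percentile was subtracted. That percentile ranged from 4.49 to 8.10 between arrays. A probe was tested if it was well above background on at least 50% of the arrays of 1 or more groups, which left 5756 probes; 1122 were well above background on all arrays. At most 21 probes were saturated on an array. For ER 40% replicates 1 and 2, 1 array each was used in the comparisons and the repeats were kept for estimates of array noise. The median SD of a probe was 0.49 between repeat arrays of one RNA and 0.76 between samples of one group. As these are arrays, their number limits the precision of every comparison.

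Changed probes were called with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3, with a mean for each of the 29 groups and a hybridization batch term in 1 model. The p-values were adjusted by Benjamini-Hochberg within a comparison, at a threshold of 0.05. Each exposed group was compared with the control group the labels assign to it, and each ER mixture with an addition also with ER 40%. One label, the sample source, describes LIS 40% as control for the 10% mixture. LIS 40% was used as the control of the 40% mixture all the same, since its title, its control field and its treatment batch place it there; LIS 10% and LIS 40% differed at 206 probes. The effect of an addition in ER was set against that in LIS as an interaction. The dose trend was a slope on the log2 of percent ER plus 1 in the dilution series. Because the replicate numbers do not pair samples (0 of 30 comparisons), no block was used.

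The toxicity score was trained on the arrays that the labels mark for training a classifier, leaving out the treatment batch of the scored array, with batches 3 and 4 left out together. The 50 probes with the most positive and the 50 with the most negative limma statistic were taken. Training used 4 to 13 toxic and 17 to 26 control arrays, and pairs of training sets shared 20 to 45 of the 50 rising and 16 to 43 of the 50 falling probes. Groups were compared by a two-sided exact permutation test of arrays, adjusted over 25 groups, and interactions by a permutation test with 100000 resamples. The latter exchanged arrays within each sediment, so its null is no effect of the addition in either, not an equal effect in both. Score differences were related to mortality over the 10 ER groups by Pearson's r and Spearman's rho, with a two-sided permutation test, which went through all orderings for the 4 or 5 groups within a batch. Mortality was compared with Fisher's exact test, with 95% exact Clopper-Pearson intervals, which cover counting error only and treat animals of a jar as independent.

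The groups, comparisons, tests, first set of alternatives and the rule for naming probes were fixed before the data were examined. The rule names the 2 probes with the largest rise and the 2 with the largest fall in toxic ER. They were taken among those past the threshold, for files without gene names. As applied, it took only probes with the same sign in all 4 differences that make up toxic ER. Of the 680 called probes, 554 had this. Levels are given with SD, and where a group had 0 arrays above background a fold is given as a lower bound, with each of its arrays set at its dimmest probe well above background. Gene lists planned for set tests were not tested, as there are no descriptions to match. The alternatives were normexp background correction, quantile normalization, the deposited values, no filter on dim probes, other batch terms and blocks, subsets of the arrays, scores with 20 or 200 probes each way or without the second tube of a jar, and each array left out in turn in groups of up to 5. The calls were tested on simulated data in which 200 probes were changed. For toxic ER, 56 of 100 changes of 1 and 96 of 100 changes of 2 on the log2 scale were recovered, with 11 false calls. Simulated probes varied independently, without batches or probes that swing together, so these false calls say little about those in the real data. Planted scores were recovered in 4 of 4 groups, and 1 of 21 other groups passed. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R with statmod 1.5.0 and the data.table package (version 1.17.8), were also used.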

Results

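Gene expression was measured in juvenile marine amphipods, Ampelisca abdita, that had survived 7 days in sediment. The control sediment came from Long Island Sound (LIS) and the toxic sediment from the Elizabeth River (ER). The 151 samples formed 29 groups of 2 to 14 arrays, each hybridized with Cy3 to a custom Agilent array that carried 7351 probes. A dilution series held 14 control arrays (LIS.Dil), 3 arrays each of ER 1.56%, ER 3.13% and ER 25%, 4 of ER 6.25% and 2 of ER 12.5%. A mixture with 10% ER had 6 arrays beside 6 of its control (LIS 10%), and the 40% mixture had 4 arrays beside 6 of LIS 40%. The 40% mixture was also tested after additions of coconut charcoal (ER.Char 40%, 6 arrays), cation exchange resin (ER.CatEx 40%, 4 arrays) and zeolite (ER.Zeol 40%, 3 arrays), which address toxicity from organic chemicals, metals and ammonia. Control sediment with the same additions had 5 or 6 arrays per group. LIS sediment amended with model toxicants had 3 to 6 arrays per group beside 5 of their control (LIS.M); the labels give no doses for them and do not say what Mdl.Deg was amended with. The share of probes well above background ranged from 26.6% to 88.2% of an array, with a median of 51.1%, and the number of arrays limits the precision of every comparison.

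The survival counts in the labels show how toxic each mixture was to whole animals. Of 60 animals in ER 40%, 86.7% died (95% exact Clopper-Pearson interval 75.4 to 94.1%), against 5.0% in LIS 40% (two-sided Fisher's exact test, adjusted p = 2.3e-20). In the dilution series 3.3% of 120 control animals died, and 0 of 30 died at ER 1.56%, where the interval reached 11.6%. Mortality was 6.7% at ER 3.13%, 30.0% at ER 6.25%, 66.7% at ER 12.5% and 90.0% at ER 25%. It exceeded the control from ER 6.25% upward (Fisher's exact test, adjusted p = 0.000288 at ER 6.25%). The labels give a single count for LIS.Dil, whose arrays came from treatment batches 3 and 4, while ER 1.56% to ER 12.5% were in batch 4. Whether the control deaths include batch 4 is not stated, but the 12 LIS.Dil jars of batch 3, with 10 animals each, already account for the 120 counted. The mortality at ER 1.56% to ER 12.5% was thus apparently tested against controls of another treatment batch only. ER 10% lost 15% of 60 animals against 1.7% in its control, which did not pass after adjustment (Fisher's exact test, p = 0.0166, adjusted p = 0.0593). Charcoal brought the mortality of the 40% mixture to 6.7% (Fisher's exact test against ER 40%, p = 3.4e-20) and cation resin to 51.7% (p = 5.6e-05), while zeolite left it at 86.7%. None of the LIS groups with an addition and none of the model toxicant groups differed from its control in mortality after adjustment over 25 groups.

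The first comparison asked which probes respond to toxic ER sediment, from the mean of 4 differences between ER 6.25%, ER 12.5% or ER 25% and LIS.Dil, and between ER 40% and LIS 40%. Of 5756 probes tested, 680 changed (limma, adjusted p under 0.05), 508 higher and 172 lower in toxic ER. Of these, 198 rose and 66 fell by at least 2-fold. Only survivors were measured, and few were left in the most toxic mixtures (3 animals in ER 25% and 8 in ER 40%). The split by direction rested on the scaling: with each array scaled on the 1122 probes detected on every array, 218 probes were higher and 555 lower. That scaling moved the median change of all probes from 0.10 to -0.16 on the log2 scale. Quantile normalization gave 372 higher and 343 lower. The total also depended on other choices: 273 probes passed with treatment batch as a term, 359 when only the groups of the comparison were fitted, and 1486 without the filter on dim probes. Normexp background correction gave 209, or 490 once spots with a very high local background, on which it had failed, were repaired. Within hybridization batches 1 and 2, with fewer arrays, 293 and 203 passed.

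Gene names are not paired with the probes in the files, so 4 probes are identified by clone name and sequence. They have the largest changes among the called probes with the same sign in all 4 differences. The largest falls were those of p79F_D10_1 (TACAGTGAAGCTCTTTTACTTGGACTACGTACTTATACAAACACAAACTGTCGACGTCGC) and p83F_G3_1 (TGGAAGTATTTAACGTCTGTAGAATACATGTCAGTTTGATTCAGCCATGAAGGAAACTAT). On the log2 scale p79F_D10_1 changed by -5.24 (SE 0.70, limma adjusted p = 3e-09) and p83F_G3_1 by -5.22 (SE 0.48, adjusted p = 4.4e-16). Both passed the threshold in all 33 alternative fits run for them. Both had 0 arrays above background in ER 40%, and p79F_D10_1 also in ER 12.5%, so the sizes of these changes are not exact. The largest rises were those of p49F_E6_1 (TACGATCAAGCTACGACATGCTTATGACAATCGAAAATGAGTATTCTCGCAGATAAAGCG), which changed by 5.12 (SE 1.38, adjusted p = 0.0057), and p48F_H5_1 (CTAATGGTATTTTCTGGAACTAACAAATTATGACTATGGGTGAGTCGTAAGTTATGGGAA), by 4.36 (SE 1.14, adjusted p = 0.0043). Each lost its call in 3 of the 33 alternatives: p49F_E6_1 with normexp correction (2.67, adjusted p = 0.050), p48F_H5_1 with the replicate numbers as a block (4.14, adjusted p = 0.057), and both within hybridization batches 1 (5.22 and 4.31, adjusted p = 0.080 and 0.075) and 2 (4.10 and 4.31, adjusted p = 0.39 and 0.22). In LIS 40% both rising probes had 0 of 6 arrays above background, so the sizes of their changes are not exact. Both of them switched between dim and bright within groups, controls included. Among the 14 LIS.Dil arrays p49F_E6_1 ranged from -5.50 to 6.73 (mean -2.89 ± 3.20, SD). In single mixtures p49F_E6_1 passed only at ER 12.5% (9.27, SE 2.86, adjusted p = 0.038, 2 arrays), where it did not with treatment batch as a term (10.39, SE 3.79, adjusted p = 0.36), and p48F_H5_1 in none.

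The signal of p83F_G3_1 separated ER from LIS sediment in most arrays. It was 2.97 ± 0.58 (SD, n = 6) in LIS 40%, 2.63 ± 1.35 (n = 14) in LIS.Dil and 2.03 ± 0.91 (n = 6) in LIS 10%, as log2 signal relative to the array's 75th percentile. In ER 40% it was above background on 0 of 4 arrays, which makes it at least 53.6-fold lower than in LIS 40% (limma, adjusted p = 1.4e-08). It was lower in every ER mixture of the dilution series (limma, adjusted p = 0.021 at ER 1.56%, change -3.03, and 3.2e-06 at ER 25%, change -5.32). At ER 1.56% replicates 1 and 2 lay at 1.86 and 0.96, within the LIS.Dil range of 0.40 to 4.83, and replicate 3 at -4.04. The call there thus rested largely on replicate 3. Falls at ER 6.25%, ER 12.5%, ER 25% and ER 40% were partly fixed in advance, since p83F_G3_1 and p79F_D10_1 were picked by them. ER 25% passed with treatment batch as a term too (change -5.59, limma adjusted p = 9.1e-07). The mixtures from 1.56% to 12.5%, which shared a treatment batch with 2 of the 14 LIS.Dil arrays, did not (changes of -1.38, -2.23, -3.55 and -2.35 with SE 1.20, 1.19, 1.13 and 1.31, lowest adjusted p = 0.58). ER 10% also had a lower level than LIS 10% (change -4.12, SE 0.78, adjusted p = 0.0016). The level was 0.74 ± 1.79 (n = 6) in ER.Char 40%, at least 11.4-fold above ER 40% (limma, adjusted p = 0.0012) while its 4.7-fold deficit against LIS 40% (change -2.23, SE 0.76) did not pass after adjustment over 5756 probes (limma adjusted p = 0.12, or 0.0040 before adjustment). ER.CatEx 40% stayed at -3.03 ± 1.89 (n = 4), and ER.Zeol 40% had 0 of 3 arrays above background, at least 52.1-fold below LIS 40% (limma, adjusted p = 5.4e-06). The effect of charcoal on p83F_G3_1 differed between ER and LIS sediment (interaction 4.44, SE 1.15, limma adjusted p = 0.023). Its size is not exact, since ER 40% had 0 of 4 arrays above background. This interaction and the contrast of ER.Char 40% with ER 40% also use the ER 40% arrays by which the probe was picked. Among the model toxicants, p83F_G3_1 fell in Mdl.Deg (change -3.11, adjusted p = 0.0098) and Mdl.Tric (-2.66, adjusted p = 0.043), and the other 7 changes did not pass. The second falling probe, p79F_D10_1, fell against LIS.Dil at ER 3.13%, ER 6.25% and ER 25% (changes -3.91, -5.14 and -5.37, limma adjusted p = 0.043, 0.0010 and 0.0020), and was at least 33.2-fold lower in ER 12.5% than in LIS.Dil (adjusted p = 0.013) and at least 17.0-fold lower in ER 40% than in LIS 40% (adjusted p = 0.0044). Of the comparisons with LIS.Dil, that of ER 25% alone passed with treatment batch as a term (limma, adjusted p = 0.0015). With that term the changes at ER 3.13%, ER 6.25% and ER 12.5% were -2.48, -3.71 and -3.98 (SE 1.75, 1.65 and 1.92). Without that term p79F_D10_1 did not pass at ER 1.56% (change -2.40, limma adjusted p = 0.24) or ER 10% (-2.50, 0.64). Nor did it in ER.Char 40% (-2.59, 0.23), ER.CatEx 40% (-4.05, 0.076) or ER.Zeol 40% (-4.01, 0.086), or between ER.Char 40% and ER 40% (2.47, 0.34).

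**Figure D1:**
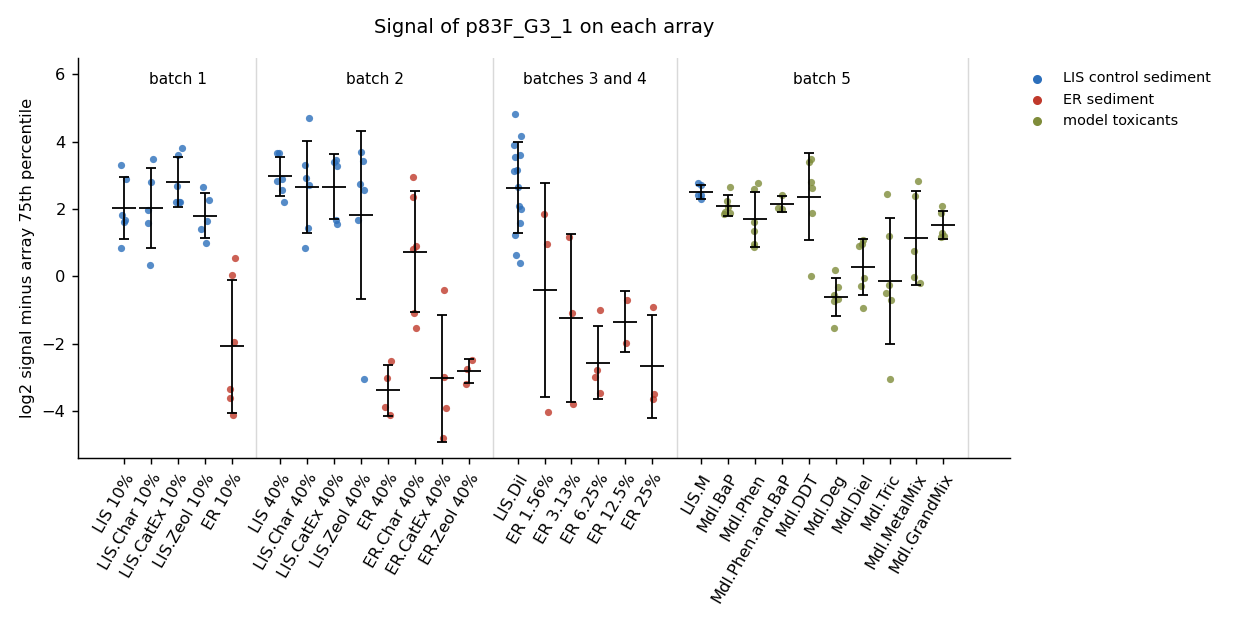
Log2 signal of p83F_G3_1 minus the 75th percentile of the array, for each array (points), with group mean and SD (bars), by treatment batch. The 6 LIS 40% arrays lay between 2.22 and 3.66 and the 4 ER 40% arrays between -4.13 and -2.52.

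Each ER mixture was then compared with its own control to see at which dilution expression changed. Against the shared LIS.Dil arrays, 294 probes changed at ER 1.56% (132 higher, 162 lower), 251 at ER 3.13% (163 and 88) and 241 at ER 6.25% (205 and 36). At ER 12.5% 289 changed (166 and 123) and at ER 25% 287 (231 and 56), all by limma at an adjusted p under 0.05. Fitted with only the groups of each comparison, where the spread was estimated from fewer arrays, the 5 counts were 60, 0, 14, 2 and 36. With normexp correction they were 4, 5, 36, 10 and 176 (49, 61, 608, 154 and 253 in the repaired version). Quantile normalization gave 442 at ER 1.56% and 700 at ER 12.5% (279 higher, 421 lower), where the deposited values gave 699 (424 and 275) and the fit without a filter on dim probes 619. With labeling batch as a term 9 were left at ER 1.56% and 38 at ER 3.13%, and with scan batch 164 and 153. ER 1.56% had 460 without the hybridization batch term, and the replicate numbers as a block gave 83 there and 128 at ER 25%. They also depended on single arrays. Without ER 1.56% replicate 1, 2 or 3 the count was 49, 133 or 94, and without ER 3.13% replicate 1, 2 or 3 it was 126, 154 or 11. ER 6.25% fell to 135 and 115 without replicates 1 and 2, and ER 25% went to 99, 441 and 96 without replicates 1, 2 and 3. ER 12.5% had 60 without replicate 1 and, without LIS.Dil replicate 6, 446. The ER 1.56%, ER 3.13%, ER 6.25% and ER 12.5% arrays came from treatment batch 4, and 12 of the 14 LIS.Dil arrays from batch 3. With treatment batch as a term, 3 probes changed at ER 1.56%, 0 at ER 3.13%, 0 at ER 6.25% and 3 at ER 12.5%. A slope on log2 percent ER across the series passed for 128 probes (106 rising, 22 falling), and for 85 without ER 12.5% replicate 2; p83F_G3_1 had a slope of -1.30 (SE 0.19, adjusted p = 0.00013). With treatment batch as a term the slope passed for 80 probes, with the replicate numbers as a block for 13, and for 1 among the arrays of batch 4 alone, which hold 2 control arrays and lack ER 25%. It passed for 58 with normexp correction and for 78 from the deposited values. Scaled on the probes detected on every array, the split by direction turned over at several dilutions: ER 3.13% had 121 higher and 176 lower probes, ER 6.25% 104 and 215, ER 12.5% 133 and 313, ER 25% 134 and 265, and the slope 38 rising and 78 falling.

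ER 10% changed 13 probes against LIS 10% (5 higher, 8 lower; 15 and 15 when scaled on the probes detected everywhere). ER 40% changed 238 against LIS 40% (149 higher, 89 lower; 161 and 174 when scaled on the probes detected everywhere), and 156 without ER 40% replicate 4. Fitted with only their own groups, ER 10% had 1 and ER 40% 102, and with normexp correction 1 and 127 (6 and 152 repaired). Within hybridization batches 1 and 2, ER 40% had 71 and 89. Because ER 40% and the dilution series share no control array, their overlap was counted. A contrast of ER 6.25%, ER 12.5% and ER 25% with LIS.Dil alone called 361 higher and 110 lower probes. Of these, 68 were also higher in ER 40%, where 9.34 would be shared by chance, and 27 were also lower, against 1.70 by chance. For 82.8% of the 471 probes the sign was the same in ER 40%, where the split by direction of all tested probes alone gives 52.6%. Scaled on the probes detected everywhere, the series called 556 probes and the share was 75.9%, against 52.9%. The same 2 shares were 86.6% and 90.3% in ER.CatEx 40% (48.0% and 54.3% from the split alone), 73.9% and 69.6% in ER.Zeol 40% (54.5% and 48.5%) and 67.7% and 70.3% in ER 10% (51.3% and 46.2%). They were 53.7% and 57.4% in ER.Char 40% (51.6% and 41.0%), and 76.4% and 70.1% in LIS.Char 40% (57.3% and 48.3%). LIS.Zeol 40% had 58.2% and 66.5% (47.3% and 47.5%), and LIS.CatEx 40% 54.4% and 57.4% (43.4% and 55.4%). All groups at 40% share the LIS 40% control. A share above the split alone was thus not particular to ER sediment.

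**Figure D2:**
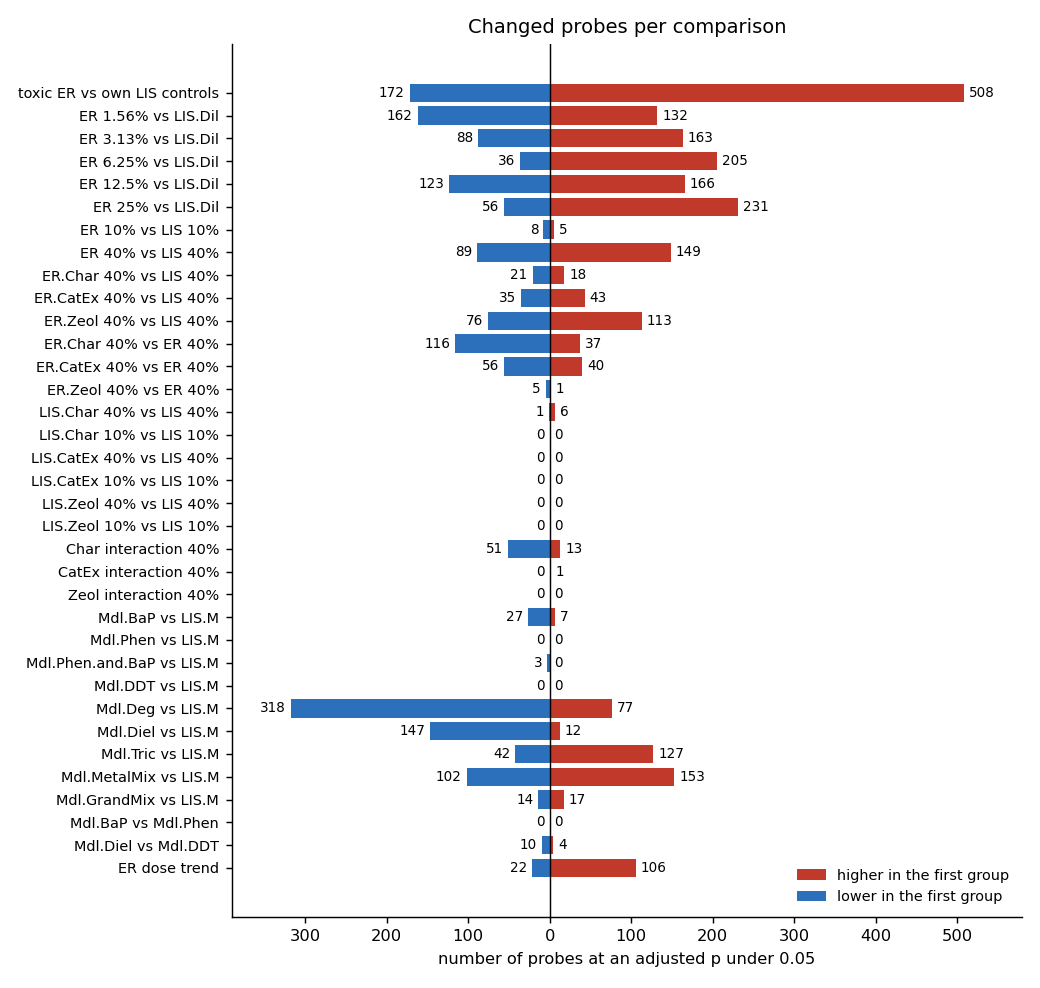
Number of probes at a limma adjusted p under 0.05 in each comparison, higher (right) or lower (left) in the first-named group. Toxic ER had 508 higher and 172 lower probes (218 and 555 when scaled on the probes detected everywhere), and 5 of the 6 LIS groups with an addition had 0.

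The additions to the 40% mixture asked which class of chemical carries the response. Against LIS 40%, 39 probes changed in ER.Char 40% (18 higher, 21 lower), 78 in ER.CatEx 40% (43 and 35) and 189 in ER.Zeol 40% (113 and 76), which fell to 73 without ER.Zeol 40% replicate 3. Fitted with only their own groups, ER.Char 40% had 7 and ER.Zeol 40% 13, and with normexp correction ER.Char 40% had 11 (24 repaired) and ER.CatEx 40% 29. Scaled on the probes detected everywhere, the 3 groups had 107 (93 higher, 14 lower), 152 (68 and 84) and 285 (136 and 149), and from the deposited values 99 (37 and 62), 118 (71 and 47) and 314 (174 and 140). Set directly against ER 40%, charcoal changed 153 probes (37 higher, 116 lower), or 65 without ER 40% replicate 2. Cation resin changed 96 (40 higher, 56 lower), with 50 and 45 left without ER 40% replicates 1 and 4, and 46, 22 and 19 without ER.CatEx 40% replicates 1, 2 and 3. Zeolite changed 6 (1 higher, 5 lower), with 3, 2 and 2 left without ER 40% replicates 1, 3 and 4, and 10, 1 and 10 without ER.Zeol 40% replicates 1, 2 and 3. These direct comparisons all but ended when only the groups of the comparison were fitted, with 1 probe for charcoal, 0 for cation resin and 0 for zeolite, and normexp correction left 23, 3 and 3 (79, 30 and 3 repaired). Quantile normalization gave 98 for charcoal (43 higher, 55 lower) and 1 for zeolite, the mean over repeat arrays 2 for zeolite, and the fit without a filter on dim probes 57 for cation resin. With each array scaled on the probes detected everywhere, the charcoal split turned to 159 higher and 45 lower probes, and cation resin had 101 and 100. In LIS sediment, charcoal changed 7 probes at 40% (6 higher, 1 lower; 1 with only its own groups fitted, 0 with normexp correction or 1 repaired, 11 with quantile normalization, 13 from the deposited values), and the other 5 additions changed 0 (limma; unadjusted p under 0.05 for 147 probes in LIS.Char 10%, 102 in LIS.CatEx 40%, 225 in LIS.CatEx 10%, 113 in LIS.Zeol 40% and 205 in LIS.Zeol 10%), although the deposited values gave 1 each in LIS.Zeol 40% and LIS.Zeol 10%. The difference between the effect in ER and that in LIS passed for 64 probes with charcoal (13 higher, 51 lower; 51 and 25 under that scaling), for 42 without ER 40% replicate 2, for 36 with quantile normalization, for 5 with only its own groups fitted and for 17 with normexp correction (23 repaired). It passed for 1 probe with cation resin (68 when scaled on the probes detected everywhere, 13 with quantile normalization, 6 from the deposited values, 4 with slide as a block, with scan batch as a term or with the mean over repeat arrays, and 0 with normexp correction or only its own groups; 2, 16, 5 and 3 without ER 40% replicates 1 to 4; 3, 0, 9 and 14 without ER.CatEx 40% replicates 1 to 4; 2 without LIS.CatEx 40% replicate 1). With zeolite it passed for 0 (limma, 198 at an unadjusted p under 0.05), with 1 from the deposited values, 3 and 1 without ER 40% replicates 2 and 4, and 2 and 3 without ER.Zeol 40% replicates 1 and 3.

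A toxicity score summarized the response in each array as the mean signal of 50 probes that rose minus that of 50 that fell in toxic training arrays of other treatment batches. Because it is a difference within the array, a common shift of all probes cancels. The score of ER 40% exceeded that of LIS 40% by 3.28 (2.93 ± 0.55, n = 4, against -0.34 ± 0.35, n = 6; two-sided exact permutation test, p = 0.0048, adjusted p = 0.013). ER 40% replicates 1 and 3 came from 2 tubes of the same jar; without replicate 3, and without the second tube of a jar in ER 6.25% and Mdl.DDT, the excess was 3.40 (exact permutation, adjusted p = 0.027). All 10 ER groups scored above their controls after adjustment over 25 groups. With 200 probes each way in place of 50, however, ER 1.56% (0.77, adjusted p = 0.064), ER 6.25% (0.70, adjusted p = 0.052) and ER 12.5% (0.78, adjusted p = 0.19) did not pass by exact permutation, nor did ER 12.5% with normexp correction (0.87, adjusted p = 0.062). In the dilution series the excess was 1.13 at ER 1.56% (adjusted p = 0.040, 2 of 3 arrays above every control array) and 1.20 at ER 3.13% (adjusted p = 0.013, 3 of 3), by exact permutation. It was 1.42 at ER 6.25% (adjusted p = 0.013, 3 of 4 arrays), 1.78 at ER 12.5% (adjusted p = 0.021, 2 of 2) and 3.26 at ER 25% (adjusted p = 0.013, 3 of 3). The ER 1.56% to ER 12.5% arrays shared their treatment batch with 2 of the 14 controls, and these tests exchanged arrays between batches. Against those 2 controls the excess was 1.52, 1.59, 1.81 and 2.16, with too few arrays to pass an exact test singly. All 12 ER arrays of that batch together exceeded the 2 by 1.74, with 11 of 12 arrays above both (exact permutation p = 0.022). The excess at ER 1.56% was no longer past the threshold without its replicate 2 (1.00) or 3 (0.68). The excess at ER 12.5% was 2.67 and 0.89 without its replicates 1 and 2, and that of ER.Zeol 40% 3.27, 3.26 and 2.87 without its replicates 1 to 3; so few arrays could not pass the exact test after adjustment, whatever their scores. ER.Zeol 40% scored 3.13 above LIS 40% (exact permutation, adjusted p = 0.027, 3 of 3 arrays) and ER.CatEx 40% 2.19 above it (adjusted p = 0.013, 4 of 4). ER 10%, whose mortality did not pass, scored 1.84 above LIS 10% (exact permutation test, p = 0.0022, adjusted p = 0.013), with all 6 arrays above every control array.

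**Figure D3:**
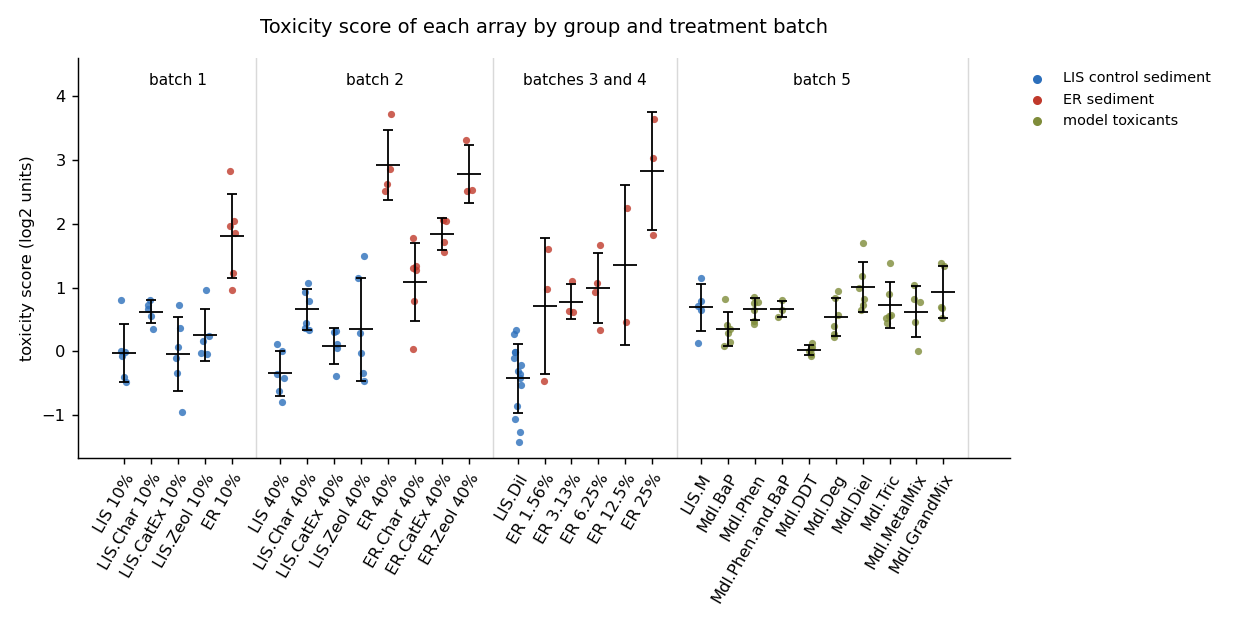
Toxicity score of each array in log2 units (points), with group mean and SD (bars), by treatment batch; each array was scored with probes chosen outside its own batch. The 4 ER 40% arrays lay between 2.51 and 3.72, and the 6 LIS 40% arrays between -0.79 and 0.11.

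Charcoal lowered the score of the 40% mixture by more than the spread between arrays, from 2.93 ± 0.55 to 1.09 ± 0.61 (difference -1.84, exact permutation test, p = 0.0048, adjusted p over 3 additions 0.014). Cation resin lowered it to 1.84 ± 0.25 (difference -1.09, exact permutation p = 0.029, adjusted p = 0.044), and zeolite left it at 2.79 ± 0.46 (difference -0.14, exact permutation p = 0.69). Without the second tube of a jar these differences were -2.02 (exact permutation p = 0.012, adjusted p = 0.036), -1.16 (p = 0.029, adjusted p = 0.044) and -0.21 (p = 0.60). ER.Char 40% still scored 1.44 above LIS 40% (exact permutation, adjusted p = 0.013, 5 of 6 arrays above every control array). Charcoal alone raised the score in control sediment, by 1.01 in LIS.Char 40% (adjusted p = 0.013, 6 of 6 arrays) and by 0.64 in LIS.Char 10% (adjusted p = 0.042, 0 of 5 arrays above every control array), both by exact permutation. The LIS.Char 10% difference did not pass without any 1 of its 5 arrays (0.60 to 0.71), with 20 or 200 probes each way (0.54 and 0.44), from the deposited values (0.33) or with either version of normexp correction (0.33 and 0.33). LIS.Char 40% did not pass with the planned normexp correction (0.38, exact permutation, adjusted p = 0.089). LIS.Zeol 40% (0.69, adjusted p = 0.14) and LIS.CatEx 40% (0.43, adjusted p = 0.10) did not pass, although LIS.CatEx 40% did without its replicate 3 (0.54). Taking the effect of the same addition in LIS sediment into account, the change in ER was -2.85 for charcoal (permutation test with 100000 resamples, p = 1e-05, the smallest they can give) and -1.51 for cation resin (p = 0.0011). For zeolite it was -0.84 (permutation p = 0.12). Without the second tube of a jar the 3 values were -2.99, -1.52 and -0.83 (permutation p = 3e-05, 0.0024 and 0.16), while the difference of LIS.Char 10%, scored with probes from the other batches, no longer passed (0.59, adjusted p = 0.054). The resampled p-values take no effect of the addition in either sediment as their null, so they do not test equal effects in both.

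Across the 10 ER groups the score excess rose with mortality (Pearson r = 0.92, permutation p = 0.00036, and Spearman rho = 0.88, permutation p = 0.0016; 2 measures of 1 relation, adjusted p of 0.0016 at most). ER 25% lay farthest from the median mortality, followed by ER 40% and ER.Zeol 40% with equal mortality. Without ER 25% and ER 40%, r was 0.86 (permutation p = 0.0049) and rho 0.81 (permutation p = 0.019), and without ER 25% and ER.Zeol 40%, r was 0.85 (permutation p = 0.0052) and rho 0.81 (permutation p = 0.018). Without all 3 groups the relation did not pass, with r at 0.73 (permutation p = 0.062) and rho at 0.72 (permutation p = 0.079) over 7 groups. Within treatment batches 3 and 4, r was 0.90 and rho 1.00 over 5 groups (exact permutation p = 0.0083 and 0.017). Within batch 2, r was 0.99 and rho 0.95 over 4 groups (exact permutation p = 0.083 and 0.17), and batch 1 held ER 10% only. Groups within a batch share control arrays. Only survivors were measured: 3 animals survived in ER 25%, with 3 arrays, and 8 each in ER 40% and ER.Zeol 40%, with 4 and 3 arrays. High mortality thus limited the number of animals behind an array. Neither this nor the selection of survivors can be told apart from the relation with mortality. The lowest r with a single array left out was 0.77, without ER 12.5% replicate 2.

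**Figure D4:**
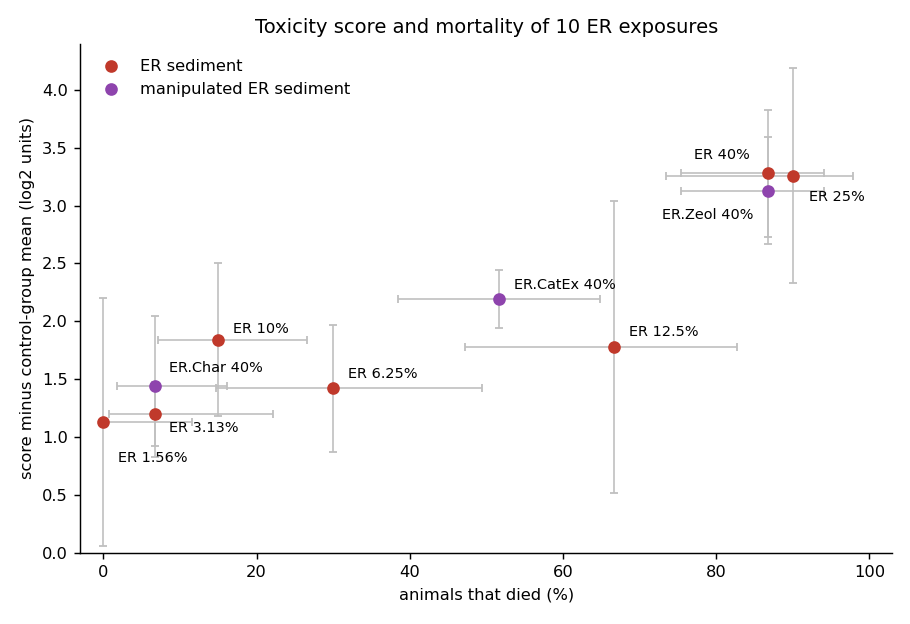
Excess of the toxicity score over the control group, in log2 units, against the percentage of animals that died, for the 10 ER groups; vertical bars are the SD of the group's arrays and horizontal bars the 95% exact interval. ER 1.56% lay at 0% and 1.13, and ER 25% at 90.0% and 3.26.

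The model toxicants asked whether known chemicals give the response of the sediment. Compared with LIS.M, 395 probes changed in Mdl.Deg (77 higher, 318 lower), 255 in Mdl.MetalMix (153 and 102), 169 in Mdl.Tric (127 and 42) and 159 in Mdl.Diel (12 and 147). Smaller numbers changed in Mdl.BaP (34; 7 higher, 27 lower), Mdl.GrandMix (31; 17 and 14) and Mdl.Phen.and.BaP (3, all lower). In Mdl.Phen and Mdl.DDT 0 changed (limma; 337 and 717 at an unadjusted p under 0.05). Single LIS.M arrays moved these numbers. Without LIS.M replicate 4 there were 599 in Mdl.Deg, 520 in Mdl.MetalMix, 373 in Mdl.Tric, 365 in Mdl.Diel, 256 in Mdl.BaP, 313 in Mdl.GrandMix, 78 in Mdl.Phen.and.BaP, 155 in Mdl.DDT and 3 in Mdl.Phen. Without LIS.M replicate 5 there were 19 in Mdl.Deg, 48 in Mdl.MetalMix, 36 in Mdl.Tric, 0 in Mdl.Diel, 0 in Mdl.BaP, 0 in Mdl.GrandMix and 1 in Mdl.Phen.and.BaP. Without LIS.M replicate 3 there were 95 in Mdl.Deg, 42 in Mdl.MetalMix, 23 in Mdl.Tric, 58 in Mdl.Diel and 0 in Mdl.BaP, Mdl.GrandMix and Mdl.Phen.and.BaP. Without LIS.M replicate 1 there were 65 in Mdl.BaP, 75 in Mdl.GrandMix, 17 in Mdl.Phen.and.BaP and 26 in Mdl.DDT, and without replicate 2 there were 81, 91, 0 and 22, with 260 in Mdl.Tric. Among the exposed arrays, Mdl.MetalMix replicates 1, 4 and 5 left 132, 148 and 145 when left out, Mdl.GrandMix replicates 1, 2, 3 and 5 left 9, 0, 10 and 9, and each of the 3 Mdl.Phen.and.BaP arrays left 0. Direction also rested on the scaling, since with the probes detected everywhere Mdl.Deg had 332 higher and 112 lower probes, Mdl.Diel 118 and 40, and Mdl.BaP 280 and 28. Mdl.DDT then had 193 and 26, Mdl.Tric 270 and 92, Mdl.MetalMix 300 and 143, Mdl.GrandMix 96 and 24, Mdl.Phen 7 and 0, and Mdl.Phen.and.BaP 1 and 0. Quantile normalization gave 54 and 19 in Mdl.BaP, 31 and 9 in Mdl.DDT, 29 and 58 in Mdl.Diel, 47 and 9 in Mdl.GrandMix and 0 in Mdl.Phen.and.BaP. The deposited values gave 45 and 26 in Mdl.BaP, 22 and 7 in Mdl.DDT, 34 and 39 in Mdl.Diel, and 4 and 2 in Mdl.Phen.and.BaP. Without the filter on dim probes Mdl.Phen.and.BaP had 753, Mdl.GrandMix 57, Mdl.Phen 3 and Mdl.DDT 2. Scan batch as a term gave 253 in Mdl.Deg, 140 in Mdl.GrandMix and 9 in Mdl.DDT, and labeling batch 72 in Mdl.GrandMix, 56 in Mdl.BaP and 2 in Mdl.DDT. With slide as a block Mdl.Deg had 255, Mdl.BaP 6 and Mdl.Phen.and.BaP 0, with the replicate numbers as a block Mdl.GrandMix had 83 and Mdl.Phen.and.BaP 0, and without the arrays with over 200 outlier spots Mdl.Diel had 96. Fitted with only their own groups, Mdl.Deg had 130, Mdl.MetalMix 3, Mdl.GrandMix 1, and Mdl.Tric, Mdl.Diel, Mdl.BaP and Mdl.Phen.and.BaP 0. With normexp correction Mdl.Deg had 66, Mdl.MetalMix 35, Mdl.Tric 44, Mdl.GrandMix 6 (2279 repaired), Mdl.BaP 1 (42 repaired), Mdl.Phen.and.BaP 0, Mdl.DDT 2 (7 repaired) and Mdl.Diel 2141 (2609 repaired). Between chemicals of one class, Mdl.BaP and Mdl.Phen differed in 0 probes (limma, 304 at an unadjusted p under 0.05; 2 with labeling batch as a term or only their own groups fitted) and Mdl.Diel and Mdl.DDT in 14 (4 higher, 10 lower in Mdl.Diel). The 14 rested on the settings: 0 were left with quantile normalization or the scaling on probes detected everywhere, 3 with only their own groups fitted and 7 without the hybridization batch term. There were 24 with the replicate numbers as a block, 51 with scan batch as a term, 22 without the arrays with over 200 outlier spots and 2190 with normexp correction (1115 repaired).

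Whether the probes called in the toxic mixtures of the dilution series kept their sign in the 9 model toxicant groups depended on the scaling. The share that did ran from 28.7% (Mdl.BaP) to 42.0% (Mdl.Tric) of 471, and from 38.5% (Mdl.Phen.and.BaP) to 59.9% (Mdl.Tric) of 556 when scaled on the probes detected everywhere. The split by direction of all tested probes alone gives 45.7% and 40.0% for Mdl.BaP, 44.8% and 50.2% for Mdl.Phen.and.BaP, and 42.6% and 53.5% for Mdl.Tric under the 2 scalings. Mdl.Deg had 37.8% and 58.6%, where the split alone gives 45.4% and 40.4%. Of the probes that were lower in the series, 24 were also lower in Mdl.Deg, against 6.08 by chance. Of those that were higher, 5 were also higher, against 4.83. Mdl.Tric shared 15 higher probes (7.97 by chance) and 4 lower (0.803), and Mdl.MetalMix 14 higher (9.6) and 2 lower (1.95). The other groups shared at most 3 in either direction. This overlap was counted under the first scaling only. The Pearson correlation of the changes over all tested probes was the same under both scalings. With the series it ran from -0.313 (Mdl.BaP) to 0.018 (Mdl.Phen) in the 9 model toxicant groups. It was 0.516 in ER 40% and 0.227 in ER 10%, but also between 0.213 and 0.335 in the LIS groups with an addition at 40%. Probes are not independent replicates. The toxicity score of 8 of the 9 groups did not differ from LIS.M after adjustment; the differences ran from -0.34 in Mdl.BaP to 0.32 in Mdl.Diel (exact permutation, adjusted p = 0.17 and 0.31). Mdl.DDT scored 0.67 lower than LIS.M (difference -0.67, 0.02 ± 0.08 against 0.69 ± 0.37, exact permutation p = 0.0043, adjusted p = 0.013). It did not pass with 20 probes each way (-0.52, exact permutation, adjusted p = 0.058) or with normexp correction (-0.40, adjusted p = 0.14). The LIS.M arrays had the highest mean score of the 4 LIS controls without additions, at 0.69, against -0.42 in LIS.Dil. These levels are not on one scale, since each batch was scored with its own probes. The sets used for LIS.M and LIS.Dil shared 30 of 50 rising and 27 of 50 falling probes.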

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

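The tests of pool size and of array noise as the whole cause, for the block of rising probes, were chosen after their results were seen. An array was set apart when its gap to the nearest array of its group was large for the range of the group, among groups of 4 to 10 arrays. This was tested 132 times, on 4 named probes, the toxicity score and the detected share, and 20 arrays stood out. Chance sets apart about 1 in 20, or 6.6 here.

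The dim arrays of p49F_E6_1 lay near background, so a single bright array stood out from its group. It was 4.89 in ER.Char 40% replicate 4 (others -4.53 to -3.32), 4.84 in LIS.CatEx 40% replicate 2, 8.10 in LIS.Char 10% replicate 3 and 5.10 in Mdl.MetalMix replicate 4. Smaller gaps set apart LIS 10% replicate 5 at 0.68 and LIS 40% replicate 6 at -2.92. For p48F_H5_1 the values were 0.64 in ER.CatEx 40% replicate 1, 3.02 in LIS 10% replicate 5, 3.47 in LIS.CatEx 40% replicate 2, 2.66 in LIS.Char 10% replicate 3 and 2.66 in Mdl.MetalMix replicate 4. In 4 arrays both probes stood out together.

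The falling probe p79F_D10_1 stood out at 1.42 in ER.CatEx 40% replicate 1, where the others lay between -4.66 and -3.66. It was -4.06 in ER 40% replicate 2, close below the others (-3.69 to -3.61). Low values were -2.18 in LIS.CatEx 10% replicate 4, 1.02 in LIS.M replicate 2 and 0.50 in Mdl.Phen replicate 4, and Mdl.GrandMix replicate 1 was high at 3.10. LIS.Zeol 40% replicate 4 had p83F_G3_1 at -3.06, where the other 5 arrays lay between 1.66 and 3.68. LIS.Zeol 10% replicate 1 had a toxicity score of 0.96 (others -0.04 to 0.24). In LIS.Zeol 40% replicate 1, 66.51% of probes were well above background (others 46.82 to 52.02%).

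With charcoal and with cation resin the score changed differently in ER and in LIS sediment, although the permutation test used does not test equal effects. The difference in score change was -2.85 for charcoal (permutation p = 1e-05, the smallest that the resamples can give) and -1.51 for cation resin (p = 0.0011), while for zeolite it was -0.84 (permutation p = 0.12) and did not pass. By limma, 64 probes differed for charcoal, 1 for cation resin, for which chance cannot be excluded, and 0 for zeolite (198 at an unadjusted p under 0.05). Repeat arrays of ER 40% entered no comparison: the lowest score of the 4 was 2.50 and the highest 2.97, while the highest of LIS 40% was 0.11. They share RNA with arrays that were compared, so they are not further samples.

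ER 1.56% and ER 3.13% differed from LIS.Dil at 294 and 251 probes, although 0 and 2 of 30 animals had died, and most LIS.Dil arrays came from another treatment batch. With treatment batch as a term, a median of 77.8% of the effect in called probes was left at ER 1.56% and 59.4% at ER 3.13%, while the SE rose from 0.39 to 0.55 and from 0.34 to 0.48, so the calls ended (3 and 0 left). Shares computed with any 2 of the 12 batch 3 controls ran from 78.5 to 140.6% and from 82.5 to 144.6% over 66 pairs (SD 14.9 and 14.3 points), all above the 2 values. At ER 1.56% the value lay close below the lowest pair, and at ER 3.13% well below it. The pairs were not refitted with a batch term, so the 2 kinds of share are not strictly alike. A contribution of treatment batch stays open, and its share cannot be told apart from that of the mixture with 2 control arrays in batch 4. With labeling batch as a term a median of 85.9% and 90.1% of the effect was left. All 3 ER 1.56% arrays and 2 of the 3 ER 3.13% arrays were in labeling batch 2, and 0 of the 14 LIS.Dil arrays. For ER 1.56% the term therefore came from other groups alone. The shares left argue against that batch as the whole cause only if it acted alike in all groups. The smaller effect and a rise of the SE to 0.44 and 0.36 ended most calls (9 and 38 left). A shared response to ER sediment stays open (74.1% and 71.7% of these probes had the same sign in ER 40%).

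The 2 named rising probes swung between arrays of a group. A block was formed of the 77 probes whose deviations from the group mean correlated over 0.6 with those of both. That the block holds these 2 probes and swings together follows from this choice. The block mean had a within-group SD of 1.61. The detected share of an array is argued against, since its correlation with the block mean within groups was 0.08 (SE 0.09). Array noise as the whole of the swing is argued against too, since the SD between repeat arrays was 0.21 of that between samples (SE 0.07, upper 95% limit 0.60), while noise as a part of it stays open, with 6 arrays of 2 RNAs from ER 40% alone. The number of animals in a tube stays open too: the SD in the model toxicant exposures was 0.95 of that in the others (SE 0.13). But the tube labels of Mdl.DDT contradict the stated pooling of all survivors of a jar there. Arrays labeled as tube b in Mdl.BaP, Mdl.Deg and Mdl.GrandMix cast doubt on it as well. No biological explanation was tested.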

How the results depend on the processing

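The always-detected scaling, the scan and labeling batch terms, the repaired normexp correction, the fits without arrays with over 200 outlier spots, those without LIS.Dil replicate 6, the scores without the second tube of a jar or with only the LIS.Dil arrays of the same treatment batch, and the 2 correlations without ER.Zeol 40% were chosen after seeing the data. A count of changed probes is called stable here within 1.5 times the reported count. Of the alternatives other than those without a single array, 318 counts were stable and 163 were not. For the scores 205 kept sign and side of the threshold, 18 lost significance, 2 gained it and 18 changed sign. Of the fits that leave out single arrays, 93 counts were stable and 84 were not, and 111 scores kept sign and side. Where no cause is given, the cause was not tested.

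Some results kept their direction in all of their alternatives and stayed past the threshold in all or most. The correlation of score and mortality ranged from 0.73 to 0.97 over 40 alternatives and passed in 39; without ER 25%, ER 40% and ER.Zeol 40% it did not (0.73, permutation p = 0.062). The score difference of ER 40% ranged from 1.96 to 4.31 and that of ER.CatEx 40% from 1.31 to 3.39, over 13 alternatives each. ER 25% ranged from 1.94 to 4.25 over 14, and ER 3.13% from 0.64 to 1.59 over 14, passing in 13. Over 9 alternatives each, ER 10% ranged from 1.07 to 2.49 and ER.Char 40% from 0.83 to 1.84. In toxic ER, p83F_G3_1 ranged from -6.06 to -2.54 (largest adjusted p 4.1e-06) and p79F_D10_1 from -5.91 to -2.54 (0.036), past the threshold in 33 of 33. The rising probes passed in 30 of 33 each, p49F_E6_1 between 2.67 and 5.64 (largest adjusted p 0.39) and p48F_H5_1 between 2.00 and 5.11 (0.22).

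Counts depended on the background correction. With normexp and an offset of 50, toxic ER had 209, ER 1.56% 4, ER 3.13% 5, ER 6.25% 36, ER 12.5% 10, ER 25% 176, ER 10% 1, ER 40% 127 and ER.Char 40% 11. ER.CatEx 40% had 29, ER.Char 40% against ER 40% 23, ER.CatEx 40% against ER 40% 3, ER.Zeol 40% against ER 40% 3, LIS.Char 40% 0, the charcoal interaction 17, the cation resin interaction 0, Mdl.BaP 1 and Mdl.Phen.and.BaP 0. Mdl.DDT had 2, Mdl.Deg 66, Mdl.Diel 2141, Mdl.Tric 44, Mdl.MetalMix 35, Mdl.GrandMix 6, Mdl.Diel against Mdl.DDT 2190 and the dose trend 58. On 6 arrays this correction failed, since 1 or more spots there had a local background of 12945 to 65273. The SD of their corrected values fell to between 0.59 and 1.08, while the 139 arrays without such spots had 1.24 to 2.24. The arrays were ER 10% replicate 5, LIS 40% replicate 3, LIS.CatEx 10% replicate 5, LIS.Dil replicate 10, LIS.Zeol 40% replicate 2 and Mdl.DDT replicate 1. These values therefore mix the choice of correction with a failed fit.

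In the repaired version, 57 spots on 12 arrays, those with a local background over 2 times the array's median, were given that median. ER 1.56% had 49, ER 3.13% 61, ER 6.25% 608, ER 12.5% 154, ER 10% 6, ER 40% 152, ER.Char 40% 24, ER.Char 40% against ER 40% 79 and ER.CatEx 40% against ER 40% 30. ER.Zeol 40% against ER 40% had 3, LIS.Char 40% 1, the charcoal interaction 23, the cation resin interaction 0, Mdl.Phen.and.BaP 0, Mdl.DDT 7, Mdl.Diel 2609, Mdl.GrandMix 2279 and Mdl.Diel against Mdl.DDT 1115. Toxic ER then had 490. The many calls in Mdl.Diel were mostly falls of similar size: 2472 of 2609 were lower, with a median change of -0.56, and in the version with the failed fits 2076 of 2141, with the 5th to 95th percentile of the changes from -0.81 to -0.39. A difference in scaling between the groups' arrays would also give falls of 1 size; the cause was not tested.

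Other sources and scalings of the values also mattered. With quantile normalization, ER 1.56% had 442, ER 12.5% 700, ER.Char 40% against ER 40% 98, ER.Zeol 40% against ER 40% 1, LIS.Char 40% 11, the charcoal interaction 36, the cation resin interaction 13, Mdl.BaP 73 and Mdl.Phen.and.BaP 0. Mdl.DDT had 40, Mdl.Diel 87, Mdl.GrandMix 56 and Mdl.Diel against Mdl.DDT 0. From the deposited value table, ER 12.5% had 699, ER.Char 40% 99, ER.CatEx 40% 118, ER.Zeol 40% 314, LIS.Char 40% 13, LIS.Zeol 40% 1, LIS.Zeol 10% 1, the cation resin interaction 6 and the zeolite interaction 1. Mdl.BaP had 71, Mdl.Phen.and.BaP 6, Mdl.DDT 29, Mdl.Diel 73 and the dose trend 78. With the 75th percentile taken over the 1122 always-detected probes, ER 12.5% had 446, ER 10% 30, ER.Char 40% 107, ER.CatEx 40% 152, ER.Zeol 40% 285, ER.CatEx 40% against ER 40% 201, the cation resin interaction 68, Mdl.BaP 308 and Mdl.Phen 7. Mdl.Phen.and.BaP had 1, Mdl.DDT 219, Mdl.Tric 362, Mdl.MetalMix 443, Mdl.GrandMix 120 and Mdl.Diel against Mdl.DDT 0.

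Whether more probes rose or fell depended on the scaling too. Over the always-detected probes, the numbers higher and lower changed by more than 10 points of share in the following results. Toxic ER had 218 and 555, ER 1.56% 87 and 272, ER 3.13% 121 and 176, ER 6.25% 104 and 215, ER 12.5% 133 and 313. ER 25% had 134 and 265, ER 10% 15 and 15, ER 40% 161 and 174, ER.Char 40% 93 and 14, ER.CatEx 40% 68 and 84. ER.Zeol 40% had 136 and 149, ER.Char 40% against ER 40% 159 and 45, the charcoal interaction 51 and 25, the cation resin interaction 27 and 41, Mdl.BaP 280 and 28. Mdl.Phen.and.BaP had 1 and 0, Mdl.Deg 332 and 112, Mdl.Diel 118 and 40, Mdl.GrandMix 96 and 24, the dose trend 38 and 78. That scaling moved the median change of all probes from -0.08 to -0.50 in ER 25%, from -0.02 to 0.41 in ER.Char 40% against ER 40%, from -0.12 to 0.31 in Mdl.BaP and from -0.14 to 0.30 in Mdl.Deg. With quantile normalization toxic ER had 372 higher and 343 lower probes, ER 12.5% 279 and 421, ER.Zeol 40% 104 and 123, ER.Char 40% 30 and 19, Mdl.BaP 54 and 19, and ER.CatEx 40% against ER 40% 46 and 33. From the deposited values ER 1.56% had 198 and 142, and Mdl.BaP 45 and 26.

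Without the filter on dim probes, toxic ER had 1486, ER 12.5% 619, ER.CatEx 40% against ER 40% 57, Mdl.Phen 3, Mdl.Phen.and.BaP 753, Mdl.DDT 2 and Mdl.GrandMix 57. Without the hybridization batch term, ER 1.56% had 460 and Mdl.Diel against Mdl.DDT 7. With slide as a random block, the cation resin interaction had 4, Mdl.BaP 6, Mdl.Phen.and.BaP 0 and Mdl.Deg 255. The labels' replicate numbers do not pair the samples (mean correlations between -0.175 and 0.218, with 0 of 30 comparisons paired). With replicate number as a block all the same, ER 1.56% had 83, ER 25% 128, Mdl.Phen.and.BaP 0, Mdl.GrandMix 83, Mdl.Diel against Mdl.DDT 24 and the dose trend 13.

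Fitted with only the groups of a comparison, each probe's spread was estimated from fewer arrays. Toxic ER had 359, ER 1.56% 60, ER 3.13% 0, ER 6.25% 14, ER 12.5% 2, ER 25% 36, ER 10% 1, ER 40% 102 and ER.Char 40% 7. ER.Zeol 40% had 13, ER.Char 40% against ER 40% 1, ER.CatEx 40% against ER 40% 0, ER.Zeol 40% against ER 40% 0, LIS.Char 40% 1, the charcoal interaction 5, the cation resin interaction 0, Mdl.BaP 0 and Mdl.Phen.and.BaP 0. Mdl.Deg had 130, Mdl.Diel 0, Mdl.Tric 0, Mdl.MetalMix 3, Mdl.GrandMix 1, Mdl.BaP against Mdl.Phen 2 and Mdl.Diel against Mdl.DDT 3. With the mean over repeat arrays, ER.Zeol 40% against ER 40% had 2 and the cation resin interaction 4. Within hybridization batch 1, with 4 of the 4 toxic mixtures present, ER 40% had 71 and toxic ER 293. Within batch 2, with 3 of them, ER 40% had 89 and toxic ER 203. Both have fewer arrays by construction. The fits without the second tube of a jar left all 3 of their counts stable.

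Treatment batch as a term gave these counts. Toxic ER had 273, ER 1.56% 3, ER 3.13% 0, ER 6.25% 0, ER 12.5% 3 and the dose trend 80. With only the LIS.Dil arrays of the same treatment batch, the counts of the single mixtures are equal to those by construction, since batch 4 keeps its 2 control arrays. ER 1.56% had 3, ER 3.13% 0, ER 6.25% 0, ER 12.5% 3, toxic ER 273 and the dose trend 1. With labeling batch as a term, ER 1.56% had 9, ER 3.13% 38, Mdl.BaP 56, Mdl.DDT 2, Mdl.GrandMix 72 and Mdl.BaP against Mdl.Phen 2. With scan batch as a term, ER 1.56% had 164, ER 3.13% 153, the cation resin interaction 4, Mdl.DDT 9, Mdl.Deg 253, Mdl.GrandMix 140 and Mdl.Diel against Mdl.DDT 51. Without the arrays with over 200 outlier spots, Mdl.Diel had 96 and Mdl.Diel against Mdl.DDT 22.

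The score lost or gained significance, or changed sign, for a few groups. With normexp, no longer past the threshold were ER 12.5% (0.87), LIS.Char 10% (0.33), LIS.Char 40% (0.38) and Mdl.DDT (-0.40); the sign changed in LIS.CatEx 10% (0.05), Mdl.Deg (0.01), Mdl.MetalMix (0.02), Mdl.Phen (0.16) and Mdl.Phen.and.BaP (0.23), with neither value past the threshold. With repaired normexp, no longer past the threshold were LIS.Char 10% (0.33); the sign changed in Mdl.Tric (-0.09), with neither value past the threshold. With quantile normalization, the sign changed in Mdl.Tric (-0.01), with neither value past the threshold. From the deposited values, no longer past the threshold were LIS.Char 10% (0.33); newly past it was LIS.CatEx 40% (0.34); the sign changed in Mdl.GrandMix (-0.06) and Mdl.Tric (-0.14), with neither value past the threshold. With 20 probes each way, no longer past the threshold were LIS.Char 10% (0.54) and Mdl.DDT (-0.52); newly past it was LIS.CatEx 40% (0.57); the sign changed in Mdl.BaP (0.01), Mdl.Deg (0.48), Mdl.MetalMix (0.34), Mdl.Phen (0.05) and Mdl.Phen.and.BaP (0.05), with neither value past the threshold. With 200 probes each way, no longer past the threshold were ER 1.56% (0.77), ER 12.5% (0.78), ER 6.25% (0.70) and LIS.Char 10% (0.44); the sign changed in LIS.CatEx 10% (0.27), Mdl.Phen (0.08) and Mdl.Tric (-0.43), with neither value past the threshold. Without the second tube of a jar, no longer past the threshold were LIS.Char 10% (0.59); the sign changed in Mdl.Tric (-0.14), with neither value past the threshold. With only the LIS.Dil arrays of the same treatment batch, which leave too few arrays to pass, no longer past the threshold were ER 1.56% (1.52), ER 12.5% (2.16), ER 3.13% (1.59) and ER 6.25% (1.81).

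Single arrays moved many counts. In the values below, slashes separate arrays of a group in the order given; for ER 12.5% without a replicate, the lone array is assumed to vary like the other groups. ER 1.56% ranged from 49 to 240, with 49/133/94 without ER 1.56% replicates 1/2/3. The dose trend ranged from 85 to 162, with 85 without ER 12.5% replicate 2. ER 12.5% ranged from 60 to 446, with 60 without ER 12.5% replicate 1 and 446 without LIS.Dil replicate 6. ER 25% ranged from 96 to 441, with 99/441/96 without ER 25% replicates 1/2/3. ER 3.13% ranged from 11 to 224, with 126/154/11 without ER 3.13% replicates 1/2/3. ER 40% ranged from 156 to 251, with 156 without ER 40% replicate 4. ER.Char 40% against ER 40% ranged from 65 to 181, with 65 without ER 40% replicate 2. ER.CatEx 40% against ER 40% ranged from 19 to 112, with 50/45 without ER 40% replicates 1/4 and 46/22/19 without ER.CatEx 40% replicates 1/2/3. ER.Zeol 40% against ER 40% ranged from 1 to 10, with 3/2/2 without ER 40% replicates 1/3/4 and 10/1/10 without ER.Zeol 40% replicates 1/2/3. The charcoal interaction ranged from 42 to 60, with 42 without ER 40% replicate 2. The cation resin interaction ranged from 0 to 16, with 2/16/5/3 without ER 40% replicates 1/2/3/4, 3/0/9/14 without ER.CatEx 40% replicates 1/2/3/4 and 2 without LIS.CatEx 40% replicate 1. The zeolite interaction ranged from 0 to 3, with 3/1 without ER 40% replicates 2/4 and 2/3 without ER.Zeol 40% replicates 1/3. ER 6.25% ranged from 115 to 276, with 135/115 without ER 6.25% replicates 1/2. ER.Zeol 40% ranged from 73 to 204, with 73 without ER.Zeol 40% replicate 3. Mdl.BaP ranged from 0 to 256, with 65/81/0/256/0 without LIS.M replicates 1/2/3/4/5. Mdl.Phen ranged from 0 to 3, with 3 without LIS.M replicate 4. Mdl.Phen.and.BaP ranged from 0 to 78, with 17/0/0/78/1 without LIS.M replicates 1/2/3/4/5 and 0/0/0 without Mdl.Phen.and.BaP replicates 1/2/3. Mdl.DDT ranged from 0 to 155, with 26/22/155 without LIS.M replicates 1/2/4. Mdl.Deg ranged from 19 to 599, with 95/599/19 without LIS.M replicates 3/4/5. Mdl.Diel ranged from 0 to 365, with 58/365/0 without LIS.M replicates 3/4/5. Mdl.Tric ranged from 23 to 373, with 260/23/373/36 without LIS.M replicates 2/3/4/5. Mdl.MetalMix ranged from 42 to 520, with 42/520/48 without LIS.M replicates 3/4/5 and 132/148/145 without Mdl.MetalMix replicates 1/4/5. Mdl.GrandMix ranged from 0 to 313, with 75/91/0/313/0 without LIS.M replicates 1/2/3/4/5 and 9/0/10/9 without Mdl.GrandMix replicates 1/2/3/5. Stable ranges were toxic ER 517 to 757, ER.CatEx 40% 55 to 66, LIS.CatEx 40% 0, LIS.Char 10% 0 and LIS.Zeol 10% 0.

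For the scores, single arrays changed the call in ER 1.56%, ER 12.5%, ER.Zeol 40%, LIS.CatEx 40% and LIS.Char 10%, by exact permutation. In Mdl.MetalMix, Mdl.Phen, Mdl.Phen.and.BaP and Mdl.Tric only the sign of a difference near 0 changed, and none of these values passed. ER 1.56% ranged from 0.68 to 1.72, with 1.00/0.68 without ER 1.56% replicates 2/3. ER 12.5% ranged from 0.89 to 2.67, with 2.67/0.89 without ER 12.5% replicates 1/2. ER.Zeol 40% ranged from 2.87 to 3.27, with 3.27/3.26/2.87 without ER.Zeol 40% replicates 1/2/3. LIS.CatEx 40% ranged from 0.36 to 0.54, with 0.54 without LIS.CatEx 40% replicate 3. LIS.Char 10% ranged from 0.60 to 0.71, with 0.66/0.63/0.71/0.62/0.60 without LIS.Char 10% replicates 1/2/3/4/5. Mdl.MetalMix ranged from -0.21 to 0.09, with 0.05 without LIS.M replicate 4 and 0.09 without Mdl.MetalMix replicate 1. Mdl.Phen ranged from -0.17 to 0.08, with 0.08 without LIS.M replicate 4. Mdl.Phen.and.BaP ranged from -0.17 to 0.09, with 0.00/0.09 without LIS.M replicates 2/4 and 0.03 without Mdl.Phen.and.BaP replicate 2. Mdl.Tric ranged from -0.10 to 0.15, with -0.10 without LIS.M replicate 1. Ranges without a change of call were ER 25% 2.85 to 3.76, ER 3.13% 1.04 to 1.29, ER 6.25% 1.20 to 1.64, the correlation with mortality 0.77 to 0.97, ER 40% 3.01 to 3.41, ER.CatEx 40% 2.12 to 2.28, Mdl.BaP -0.48 to -0.22, Mdl.DDT -0.81 to -0.55, Mdl.Deg -0.28 to -0.03, Mdl.Diel 0.18 to 0.44, Mdl.GrandMix 0.10 to 0.35 and LIS.Zeol 10% 0.10 to 0.35. A lone ER 12.5% array against 14 controls cannot pass an exact test, and neither can 2 ER.Zeol 40% arrays against 6 after adjustment, since even with both above every control array the adjusted p was 0.069, so these 2 groups show nothing about stability here.

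Planned tests of gene lists were not run, because no probe has a gene name or description. The dose trend was not run with the labeling or scan batch term. Signal over background limits the dim probes: 5756 of 7351 were tested, and a fold against a group with 0 arrays above background is a lower bound. In simulated data with planted changes, the comparison of ER 40% with LIS 40% recovered 11 of 100 probes changed by 1 on the log2 scale and 65 of 100 changed by 2, so a count of 0 leaves room for changes of the smaller size.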

Other observations

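All counts of splits, the comparisons between control groups and the test of probes that overlap on the same strand were chosen after the results were seen. For each comparison the arrays were divided into groups of the same sizes in other ways, and the number of divisions with as many changed probes was counted, the real one included. At most 100 were drawn.

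Few splits, the real one included, were as large for toxic ER (680 probes, 1 of 100 splits, highest other 513). This was also so for ER 40% (238, 1 of 100, highest other 68) and ER 10% (13, 4 of 100, highest other 27). The same holds for ER.Char 40% (39; 1 of 100, highest other 9), ER.CatEx 40% (78; 1 of 100, 27) and ER.Zeol 40% (189; 1 of 84, 62), each against LIS 40%. Against ER 40% it holds for ER.Char 40% (153; 4 of 100, 860) and ER.CatEx 40% (96; 1 of 35, 94). It also holds for LIS.Char 40% (7; 2 of 100, 48), the charcoal interaction (64; 2 of 100, 224) and the dose trend (128; 1 of 100, 8). Among the model toxicants it holds for Mdl.Deg (395 probes, 2 of 100, 592), Mdl.MetalMix (255, 1 of 100, 191) and Mdl.Diel against Mdl.DDT (14, 2 of 100, 17). These shares were not adjusted over the comparisons, and at most 100 splits were drawn, so they cannot exclude chance for any single one. In several, another split gave more probes than the real one. For toxic ER and the dose trend the splits exchanged arrays between treatment batches, so they say nothing about batch.

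In the dilution series the share was under 0.05 for ER 1.56% (294 probes, 2 of 100 splits, highest other 1811), but this says nothing about treatment batch. The splits exchanged arrays between batches, and with treatment batch as a term 3 probes were left at ER 1.56%, 0 at ER 3.13%, 0 at ER 6.25% and 3 at ER 12.5%. With labeling batch as a term 9 were left at ER 1.56%. Chance cannot be excluded for ER 3.13% (251; 9 of 100, highest other 1446), ER 6.25% (241; 5 of 100, 746) or ER 25% (287; 5 of 100, 2586), and for ER 12.5%, with 2 arrays, the splits were not counted. Other splits with several times the real count point to a structure of the samples. In the 4 comparisons, 17 other splits were as large, and in 13 of them LIS.Dil replicate 6 had been moved to the small group, as it was in 82 of all 396. Without LIS.Dil replicate 6 there were 240 changed probes at ER 1.56%, 224 at ER 3.13%, 276 at ER 6.25%, 446 at ER 12.5% and 258 at ER 25%.

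Chance cannot be excluded for ER.Zeol 40% against ER 40% (6; 23 of 35 splits, highest other 137), the cation resin interaction (1; 41 of 100, 98), Mdl.BaP (34; 14 of 100, 370) and Mdl.Phen.and.BaP (3; 11 of 56, 700). The same applies to Mdl.Diel (159; 6 of 100, 685), Mdl.Tric (169; 8 of 100, 333) and Mdl.GrandMix (31; 12 of 100, 261). For counts of 0 all 100 of 100 splits are as large by construction. The highest other count, by limma, was 1 for LIS.Char 10% (147 probes at an unadjusted p under 0.05 in the real split), 21 for LIS.CatEx 40% (102), 1 for LIS.CatEx 10% (225), 52 for LIS.Zeol 40% (113) and 1 for LIS.Zeol 10% (205). It was 68 for the zeolite interaction (198), 135 for Mdl.Phen (337), 98 for Mdl.DDT (717) and 55 for Mdl.BaP against Mdl.Phen (304). Splits of the model toxicant arrays that gave several times the real count, as in Mdl.BaP and Mdl.Phen.and.BaP, also point to a structure of the samples.

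The 4 LIS controls without additions, from different treatment batches, differed from each other. LIS 10% and LIS 40% differed at 206 probes (1 of 100 splits, highest other 107), LIS 10% and LIS.Dil at 31 (3 of 100, 77), and LIS 10% and LIS.M at 774 (1 of 100, 447). LIS 40% and LIS.Dil differed at 601 (3 of 100, 1061), LIS 40% and LIS.M at 1237 (1 of 100, 1121), and LIS.Dil and LIS.M at 1693 (1 of 100, 798). Under 0.05 of the splits were as large in all 6, again without adjustment. Between the 2 LIS.Dil arrays of batch 4 and the 12 of batch 3, 0 probes changed (limma, 511 at an unadjusted p under 0.05).

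Probes whose clone name holds an R were dimmer than those with an F, with medians of -3.66 (3654 probes) and -0.95 (3675 probes), a gap of 2.72 on the log2 scale. Base composition is argued against, since the gap between probes of equal GC content was 94.2% of that. R probes carrying the strand opposite to the labeled RNA is a candidate explanation that stays open. In 60 pairs of probes that are reverse complements over at least 20 bases, F was brighter in 80% (SE 5.2 points), but 77.3% of all possible F and R pairs also have the brighter F. Where F and R probes overlapped on the same strand, F was brighter in 18 of 26 pairs (69.2%), which leaves an effect of the name itself open. Of the tested probes, 14.3% of those named F and 8.4% of those named R were called in toxic ER, after a filter that kept 91% of all F and 65.6% of all R probes.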
